A study of Homo sapiens with 16 samples.

How the data were processed

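RNA was sequenced from 16 cultures of hTERT-RPE1, an established, telomerase-expressing and non-transformed human retinal epithelial cell line. In these cells endogenous RB, the retinoblastoma protein, was knocked down and replaced by an exogenous form through inducible constructs, with 0.5 µg/ml doxycycline for 48 h in medium with 5% serum, per the labels' protocols. The 16 forms were wild-type RB (WT), the constitutively active RBΔcdk (dCDK) and 14 mono-phosphorylation isoforms, each named for a single serine or threonine (S230 to T826). Each form had 1 sample, taken from its title, so no comparison of 1 form with another had a replicate.

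The authors deposited 1 table of 57600 genes by 16 samples with Ensembl gene identifiers and symbols. Its values are a signal, reads per gene divided by a size factor for each sample, per the file headers, which name them normalised counts. The submitters' processing notes name Trimmomatic 0.3, TopHat2 2.01, HTSeq, DESeq2 and the build GRCh38. Libraries were made from total RNA with a TruSeq kit, per the labels' protocols. The annotation release, the strand setting and any pooling of runs are not given in the sources used here. Antisense and overlapping genes were therefore treated as uncertain, as were near-identical genes such as histones and pregnancy-specific glycoproteins, whose reads counting can lose or split.

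In every sample 100% of the values above 0 were whole multiples, within a tolerance of 0.01 reads, of the value of 1 read. Whole reads were recovered by division, and summed to between 7191645 (S608) and 15878165 (WT), with a median of 10759885. All 16 columns matched a sample title. Every pair of libraries differed beyond sampling noise, with at least 2.752 chi-square units per gene, the lowest for T821 and T826. Genes were placed on GRCh38 with GENCODE release 29, which held 56996 of the 57600 identifiers (99.0%) and 10524 of the 10536 genes analysed.

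Values were compared as log2(value + 10) over the 10536 genes with a mean of at least 50 over the 16 samples, so that fold changes of low genes are understated. For each form against WT, and against the median of the other 15 samples, genes at least 2-fold apart were counted, without a p-value. Ratios of normalised counts carry exact Clopper-Pearson 95% intervals of the reads, which cover counting error only. A further 26 gene lists were fixed before the data were examined, as were the rules below and the planned tests and alternatives. Tests and alternatives chosen after the data were seen are named as such below. The median difference of each list was placed among 10000 random lists of the same size matched on expression deciles. This percentile describes the libraries and is not a p-value.

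The lists covered E2F targets of G1/S, G2/M genes, replication-dependent histones, homologous recombination and fork repair, p53 targets, RB family with E2F and DREAM factors, and NuRD subunits. They also covered nuclear subunits of complex I and of complexes II to V of oxidative phosphorylation (OXPHOS), mitochondrial DNA-encoded proteins, the mitochondrial ribosome, cytosolic ribosomal proteins, the TCA cycle, glycolysis, hypoxia and cholesterol synthesis. The rest were the ATF4 response, the unfolded protein response, heat shock, interferon, inflammatory targets, extracellular matrix, immediate early genes, lysosome and autophagy, pigment epithelium markers, and markers of other cell types.

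Named genes were chosen by rule. These were RB1 and its family, the 10 highest and 10 lowest genes of dCDK against WT, and the 2 highest and 2 lowest of each isoform against the other 15 samples. They also included the 3 members of each list with the largest median difference, the 10 largest in each direction among genes on the same side of WT in all 14 isoforms, and the 5 smallest p of the C-terminal comparison. Clone names were left out of the ranking of dCDK and of single isoforms. Some genes chosen by these rules are not reported here.

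The 7 isoforms at residue 780 or beyond (C-terminal) were tested against the 7 below it with limma 3.58.1 (trend) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. The spread between isoforms served as the error. Gene lists were tested with camera, at its preset correlation of 0.01 and at an estimated correlation. edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads as alternatives. On simulated counts for this comparison, with 200 of 10536 genes changed, limma recovered 90% of the genes changed 1.5-fold and 100% of those changed 2-fold, called 8 unchanged genes, and called 0 genes where nothing was changed. The simulated genes varied independently of each other and no library was shifted as a whole. These rates therefore do not give the power in the real libraries, where genes of a list moved together. List scores, the mean over members of centred log2 values, were correlated across samples with permutation tests of 100000 resamples (Python 3.11.15, numpy 2.4.6, scipy 1.17.1). On simulated scores for 24 lists the correlation script made 0 calls without a relation and found the 1 built in.

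Alternatives covered a pseudocount of 1, means of at least 10 or 200, no filter, equal totals, upper quartile scaling, 1.5-fold, the mean over members, another reference, and leaving samples out. A planned fit of each form against WT with replicates could not be made, since the table holds 1 column per form.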

Results

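The series asked how transcription in RPE1 cells changes when endogenous RB is replaced by wild-type RB, by constitutively active RBΔcdk (dCDK), or by any of 14 mono-phosphorylation isoforms. RB restrains E2F transcription factors and thereby entry into S phase. RNA was measured in 16 libraries, 1 for each form, so differences from wild type (WT) have no replicate check. Depth ran from 7191645 recovered reads (S608) to 15878165 (WT). Between 18822 (S811) and 22946 (WT) genes had reads. Values are normalised read counts, and log2 differences are on the log2(value + 10) scale.

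RB1, the gene replaced (ENSG00000139687, GRCh38 chromosome 13, 48303726 to 48599436, plus strand), was read in all 16 libraries. Its normalised count was 1714 in WT, 3063 in dCDK and 2821 ± 621 over the isoforms (SD, n = 14 isoforms). Among the isoforms it was lowest in S780, at 1755, and highest in S795, at 4099. The ratio to WT was 1.02 in S780, with a 95% counting interval of 0.961 to 1.09, and 2.39 in S795, with an interval of 2.27 to 2.51. Endogenous and exogenous transcripts are counted together and every library carries a replacement, so these values do not check the knockdown.

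Among the RB family, E2F and DREAM factors, several genes that drive the cycle were lower than WT, and so was the RB relative RBL1. MYBL2, a transcription factor of late cell-cycle genes, was 1453 in WT, 241 in dCDK and 304 ± 118 over the 14 isoforms. E2F1, an activator E2F, was 668 in WT, 156 in dCDK and 214 ± 70.1 over the isoforms. CCNE2, which encodes cyclin E2, was 435 in WT and 61.0 in dCDK. RBL1, which encodes p107, was 579 in WT and 206 ± 65.9 over the isoforms. RBL2, E2F4 and E2F3 lay closer to WT, with medians over isoforms of -0.15, -0.17 and -0.23 log2. CDK6, a cyclin D kinase, was 2232 in WT and 3128 ± 602 over the isoforms, with 1281 in S811, the lowest. The list of 23 measured members had a median of -0.37 in dCDK and -0.34 over the isoforms, under the lowest 2.5% of matched random lists in all 14.

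The next comparison asked what constitutively active RB does against wild type. In the dCDK library E2F targets of G1/S and replication-dependent histones were far lower than in WT, and most p53 targets and CDK inhibitors were higher. PRIM1, the catalytic subunit of DNA primase (ENSG00000198056, chromosome 12, 56731596 to 56752373, minus strand), was 39.8 against 344 in WT, a ratio of 0.116 with a 95% counting interval of 0.0832 to 0.157. CDKN1A, the CDK inhibitor p21 (ENSG00000124762, chromosome 6, 36676460 to 36687339, plus strand), was 8213 against 1599, 5.14-fold higher (4.91 to 5.37). BTG2, an antiproliferative p53 target, was 171 against 27.6.

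In all, 570 genes lay at least 2-fold apart, 162 higher and 408 lower in dCDK. The 10 lowest were PRIM1, WDR76, CCNE2, FAM111B and the histone genes HIST1H2BM, HIST2H2BF, HIST1H2BG, HIST1H2AL, HIST2H3D and HIST1H2AJ, with log2 differences from -2.93 to -2.56. Histone values are uncertain where near-identical copies share reads. The 10 highest were ARHGEF3, CDKN1A, BTG2, PSG4, MELTF, NEAT1, CPA4, C3, CNN1 and TP53INP1, with log2 differences from 3.46 to 1.91. C3 encodes complement component 3, with 776 in dCDK and 195 in WT. NEAT1, a nuclear long noncoding RNA, was 28530 in dCDK and 6930 in WT. The PSG4 value may include reads of its close relatives.

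The gene lists gave the same picture of dCDK. Of 46 measured E2F targets of G1/S, 46 were lower than WT and 41 at least 2-fold lower, with a median of -1.71. Of 44 G2/M genes, 44 were lower, with a median of -1.23. The 27 histones had a median of -2.12, and 26 were at least 2-fold lower. The 32 genes of homologous recombination and fork repair had a median of -1.16. The 30 p53 targets and CDK inhibitors had a median of 0.61, with 25 higher, 8 of them at least 2-fold, and 5 lower, 2 of them at least 2-fold. The cell-cycle and repair lists lay below all of the 10000 matched lists, and the p53 list above all of them. With the median of the other samples in place of WT, the E2F median of dCDK was -0.40, since the isoforms differed from WT in the same direction.

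**Figure D1:**
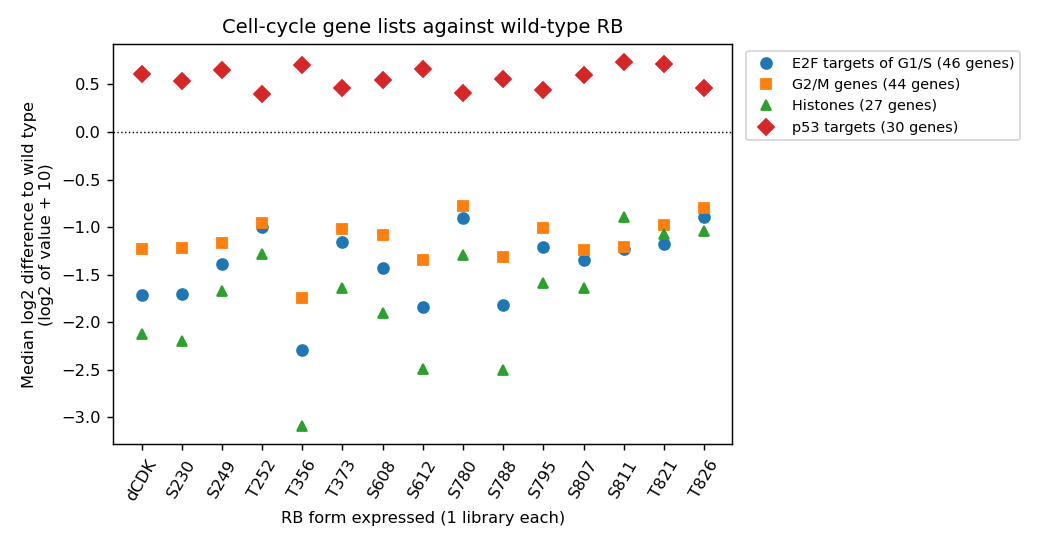
Median log2 difference to wild type (vertical axis, log2 of value + 10) of 4 gene lists in each of the other 15 libraries (horizontal axis), 1 point per list and library, with the dotted line at 0 for wild type. E2F targets, G2/M genes and histones lie below 0 and p53 targets above 0 in all 15, and T356 holds the lowest E2F median, -2.30.

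The comparison of the 14 isoforms with WT asked which transcripts differ when RB carries a single phosphate. Every isoform library had lower replication and mitosis transcripts than WT and higher p21. CCNE2 was 120 ± 54.1 over the isoforms against 435 in WT. CDT1, a licensing factor for replication origins, was 92.8 ± 31.2 against 370. PLK1, a mitotic kinase, was 499 ± 121 against 1634. CDKN1A was 7152 ± 2053 against 1599. The SDs are over 14 isoforms with 1 library each, not over replicates.

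The number of genes at least 2-fold from WT had a median of 486.5 over the isoforms, from 245 in S780 to 956 in T356. More were lower than higher in each isoform, with medians of 337 and 150.5. In S811 the split was 360 higher and 555 lower, and with equal totals per sample it was 197 and 825. With dCDK as the reference the counts were far smaller, with a median of 22.5, from 7 in S249 to 323 in S811.

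**Figure D2:**
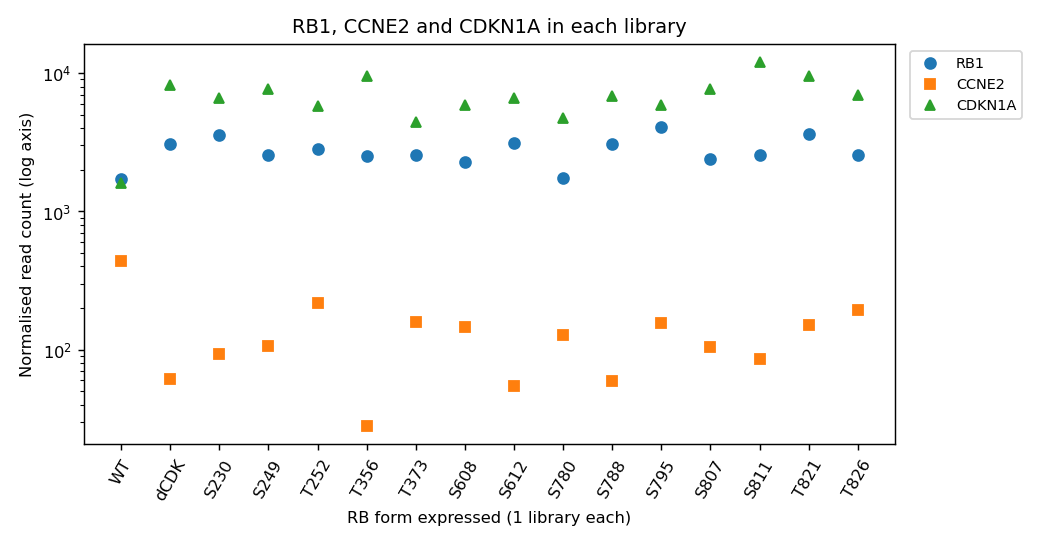
Normalised read counts (vertical log axis) of RB1, CCNE2 and CDKN1A in each of the 16 libraries (horizontal axis), 1 point per gene and library. CCNE2 is highest in WT, at 435, and CDKN1A lowest in WT, at 1599, while RB1 runs from 1714 in WT to 4099 in S795.

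The E2F targets had a median of -1.29 over the isoforms, with a mean of -1.39 ± 0.40 (SD, n = 14 isoforms). The lowest was T356, at -2.30, followed by S612 at -1.84 and S788 at -1.82, each below dCDK. The nearest to WT were T826 and S780, each at -0.90. Of the 46 members, 45 were lower than WT in all 14 isoforms. The largest differences were in PRIM1, with a median of -1.85, CDT1, with -1.83, and CCNE2, with -1.81. G2/M genes had a median of -1.13, and 44 of 44 members were lower in all 14 isoforms, with MYBL2 (-2.20), PLK1 (-1.69) and KIF20A (-1.66), a mitotic kinesin, the farthest. Histones had a median of -1.64, from -3.09 in T356 to -0.89 in S811, with HIST2H3D (-2.09), HIST1H3H (-1.93) and HIST1H2AH (-1.92) the farthest. Recombination and fork repair genes had a median of -0.86, led by the Fanconi anaemia genes FANCA (-1.50) and FANCE (-1.26) and by RAD54L (-1.24). Each of these 4 lists lay in the lowest 2.5% of matched lists in 14 of 14 isoforms. The E2F median over isoforms was 0.0045 when each isoform was set against the median of the other 15 samples.

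Lists higher in most isoforms by their median included p53 targets, extracellular matrix and TGF-beta genes, and interferon genes. The 30 p53 targets and CDK inhibitors had a median of 0.55, with CDKN1A (2.07), BTG2 (1.99) and ZMAT3 (1.62), an RNA-binding p53 target, the farthest. The 25 extracellular matrix and TGF-beta genes had a median of 0.51, with CNN1 (2.27), which encodes calponin 1, and TGFBI (0.98) among the farthest. Both lists lay in the highest 2.5% of matched lists in all 14 isoforms. The 19 interferon genes had a median of 0.40 and reached that range in 12 isoforms, with SAMD9L (1.48), TRIM22 (1.32) and IFIT2 (1.24) the farthest. The 28 lysosome and autophagy genes had a median of 0.24, in that range in 9 isoforms. GABARAPL1, an autophagy gene, was 267 ± 46.1 against 82.2 in WT, NEU1 had a median of 0.90 and ATP6V1A 0.77. The 6 measured pigment epithelium markers had a median of 0.50, although PAX6 was lower (-0.73). RDH5 (0.88) and KRT8 (0.68) were higher.

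Genes of the ATF4 and integrated stress response were lower than WT by their median. Of the farthest members, PSAT1, of serine synthesis, was 547 ± 147 over the isoforms against 1589, and ASNS, asparagine synthetase, 326 ± 94.5 against 815. PCK2 had a median of -1.42. The 27 genes had a median of -0.58, with 4 at least 2-fold lower by median, and lay in the lowest 2.5% in 14 of 14 isoforms. The 13 NuRD subunits had a median of -0.35, in that range in 13, with the histone-binding proteins RBBP7 (-0.87) and RBBP4 (-0.49), which belong to other complexes too, and MBD3 (-0.65) the farthest.

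In all 14 isoforms 23 genes were at least 2-fold higher and 57 at least 2-fold lower than WT. The same 23 and 57 were also 2-fold apart in dCDK. All these comparisons share the single WT library. In 100 simulations of unchanged groups against a shared control the counts averaged 0.26 and 0.37, with highest values of 2 and 3. Independent lists would share 7.7e-22 and 8.1e-18 genes. These figures do not allow for a control library that itself differs. With S811 in the place of WT, 50 genes were at least 2-fold higher and 0 lower in the other 13 isoforms, with T356 the counts were 1 and 6, and with each of the other 12 isoforms at most 3 in either direction. How much of the 23 and 57 comes from the WT library is open. The 10 highest by median were CNN1, CDKN1A, SPP1, BTG2, PSG4, SLC16A4, CPA4, C1S, MAP1A and KCTD4. SPP1, which encodes osteopontin, was 82.2 ± 32.4 over the isoforms and 11.4 in WT. The 10 lowest were HIST1H2BM, MXD3, MYBL2, NEURL1B, HIST2H3D, TMPO-AS1, HIST2H2BF, HIST1H2AJ, HIST1H2BL and LMNB1. LMNB1, lamin B1 of the nuclear envelope, was 502 ± 183 against 1976. TMPO-AS1 lies antisense to TMPO, and without the strand setting their reads may be mixed. Of the 57 lower genes, 24 belonged to the E2F, G2/M or histone lists, which held 117 tested members.

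Other lists lay near WT in most isoforms. Medians over the isoforms were 0.04 for 19 TCA cycle genes (MPC1 0.40, PDHX 0.37, DLD 0.35), -0.12 for 19 glycolysis genes (ENO2 -0.85, SLC2A3 0.81, ENO1 -0.53) and 0.14 for 15 hypoxia genes (P4HA2 0.73, P4HA1 0.70, BNIP3L 0.65). They were 0.08 for 24 cholesterol genes (TMEM97 -0.92, PMVK -0.76, MSMO1 0.71), 0.07 for 20 unfolded protein response genes (DNAJB9 0.73, DNAJC3 0.50, SDF2L1 -0.47) and -0.04 for 18 heat shock genes (CRYAB 0.67, HSPB1 -0.35, HSPA1B -0.34). They were -0.07 for 16 inflammatory genes (IL1A, 88.5 ± 21.5 over the isoforms and 39.1 in WT, LIF 0.92, CSF2 0.52) and -0.17 for 15 immediate early genes (KLF6 -0.80, FOSL1 -0.73, JUN -0.54). Glycolysis lay in the lowest 2.5% in 7 isoforms and immediate early genes in 3, while hypoxia and cholesterol genes lay in the highest 2.5% in 3 isoforms each. Of 30 markers of other cell types, 0 passed the filter and 28 stayed under 20 in every library. PTPRC, a leukocyte marker, reached 86.6 in S811, from 62 reads. HBB, of erythroid cells, reached 47.3 in S807, with 40.6 and 40.5 in other libraries and at most 0.763 elsewhere.

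Nuclear genes of the respiratory chain and of the ribosome were higher in S811, T821 and T826 and near WT in the other isoforms. The 35 measured complex I subunits had a median of 0.03 over the 14 isoforms, with 0.73 in S811, 0.30 in T821 and 0.27 in T826. Subunits of complexes II to V had a median of 0.08, with 0.65, 0.34 and 0.35 in these libraries. The 75 cytosolic ribosomal proteins had a median of 0.11, with 0.76, 0.38 and 0.38. All 3 lists lay in the highest 2.5% of matched lists in these 3 isoforms and in no other. Mitochondrial ribosome genes had a median of -0.09, with 0.43 in S811, 0.07 in T821 and 0.13 in T826. Their farthest members were MRPS21 (-0.42), MRPL16 (-0.40) and MRPL23 (-0.36).

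The 13 transcripts encoded by mitochondrial DNA went the other way. Their median was 0.44 over the isoforms, from 0.84 in S230 to -0.20 in S811, -0.22 in T821 and -0.03 in T826. MT-ND4, a complex I subunit, was 1924 ± 603 over the isoforms and 1131 in WT. MT-ND2 had a median of 0.77 and MT-ND1 0.69. The list lay in the highest 2.5% of matched lists in 11 isoforms and in the lowest 2.5% in T821. Among nuclear-encoded members, the farthest by median were NDUFB5 (0.36), NDUFB3 (0.36) and NDUFS6 (-0.35) of complex I, and COX8A (-0.48), SDHA (-0.43) and SDHC (0.41) of the others. Those of the cytosolic ribosome were RPS24 (0.44), RPL7 (0.40) and RPS16 (-0.34).

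The same 3 libraries had the lowest values of NEAT1 and MALAT1, long noncoding RNAs kept in the nucleus. NEAT1 was 1963 in S811, 2520 in T821 and 1753 in T826, against 6930 in WT and a median of 18528 over the other 11 isoforms. MALAT1 was 8857, 16298 and 13333, against 21948 in WT and a median of 47434 over the other 11. RN7SK, a small nuclear RNA, took 3.22%, 2.96% and 2.90% of their reads, 2.78% in WT, and 1.81% in S230, the lowest. MEG3, another long noncoding RNA, was 493, 543 and 505 in S811, T821 and T826, against 529 in WT and a median of 1306 over the other 11. The score of mitochondrial DNA-encoded transcripts was -0.65, -0.63 and -0.44 in these 3, -0.34 in WT and -0.04 in S249, the next lowest. WT thus shared part of this pattern. How far the differences of these transcripts from WT come from the WT library is open.

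**Figure D3:**
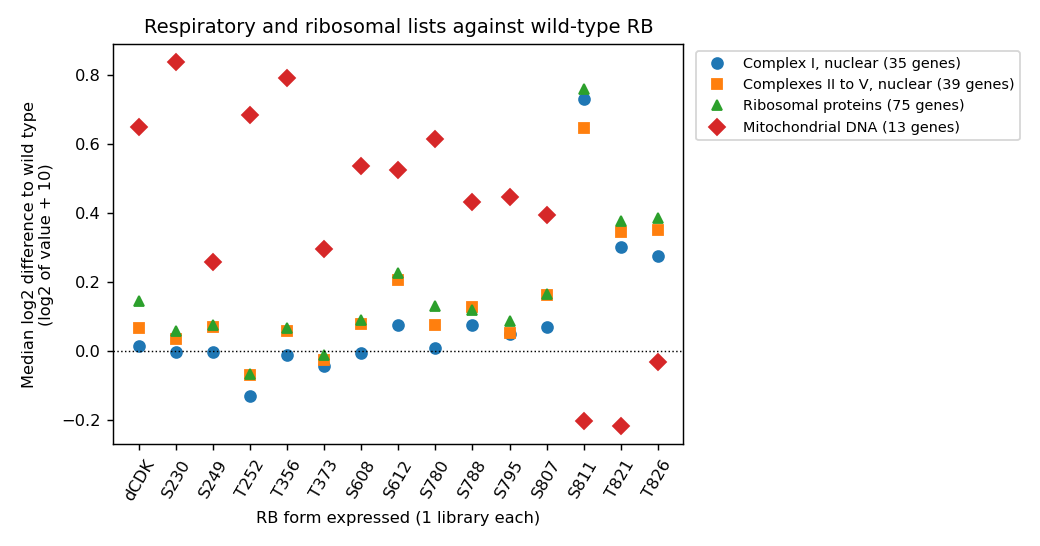
Median log2 difference to wild type (vertical axis, log2 of value + 10) of respiratory and ribosomal gene lists in each of the other 15 libraries (horizontal axis), 1 point per list and library, with the dotted line at 0 for wild type. The 3 nuclear lists reach 0.73, 0.65 and 0.76 in S811, while transcripts of mitochondrial DNA lie at -0.20 there.

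To ask what sets single isoforms apart without WT as the only reference, each was compared with the median of the other 15 samples, WT included. The median count of genes 2-fold apart was 10, from 1 to 334. S811 had 20 higher and 314 lower, and T356 16 higher and 106 lower. WT itself had 323 higher and 136 lower. In S811 the highest were SELM, a selenoprotein, and CNN1, and the farthest below NEAT1 and MALAT1. In T356 the highest were LINC01435 and KMT2C, a histone methyltransferase, at 3759 against no more than 1000 elsewhere. Farthest below were the histone genes HIST1H2BG and HIST1H3H.

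The highest genes of the other isoforms, by log2 difference to the median of the other 15 samples, were of many kinds. PLA2G6, a phospholipase, was 362 in T826 against at most 53.6 elsewhere, and C3orf62 was 200 there. SPEF2 was 351 and DECR2 336 in S788, DGKI 955 and EFCAB7 185 in S795, and TMEM67 360 and FSD1L 379 in S608. CEP83 (450) and FMN1 (325) led in S612, MGA (924) and ARHGAP32 (318) in T373, PLXNA4 (523) and PTX3 (703) in S780, and GDF6 (506) and PDPK1 (1271) in S230. KISS1 (164) and WDR66 (334) led in S807, IFIT1 (215) and KRT81 (1547) in T821, MIAT (191) and COL6A1 (107) in S249, and LINC00702 (392) and FAM111B (364) in T252.

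The genes of each isoform farthest below the median of the other 15 samples were not always at their lowest value there. In T373 CSF2, a growth factor of myeloid cells, was 9.96 against a median of 74.4 elsewhere, and the chemokine CXCL8 315 against 929. In T252 PLAU, the urokinase gene, was 1472 against 3365 and RNY1 92.4 against 230. In S612 the farthest below that median were HIST1H2AB (138) and ORC1 (38.5), in S788 HIST1H3C (297) and HIST1H2AL (114), and in S230 HIST1H2AE (276) and HIST1H2BM (62.6). In S780 they were HSPB7 (72.0) and MEIS3 (76.5), in S795 SERPINB2 (148) and HSPB7 (81.0), and in S807 RNY1 (118) and NCKAP1L (37.6). In S249 they were KCNQ3 (29.6) and ELOVL7 (59.1), and in S608 RNU5E-1 (45.4) and SNORA23 (38.1). In T821 they were NEAT1 and LENG8 (138), and in T826 NEAT1 and GOLGA8B (17.0).

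The comparison of the 7 C-terminal isoforms with the other 7 asked whether the position of the phosphate goes with a difference in transcription. No gene passed the adjusted threshold with limma (0 of 10536 genes, 1690 at an unadjusted p under 0.05). edgeR on recovered reads gave 0 and DESeq2 gave 51, of which 4 were higher and 47 lower in the C-terminal isoforms. Leaving out S788 gave 20 genes and leaving out S612 gave 3. The smallest limma p belonged to CH507-513H4.5, at 153 ± 45.3 in the C-terminal and 49.9 ± 44.3 in the other isoforms (n = 7 each), with a log2 difference of 1.61 ± 0.27 (SE) and a limma adjusted p of 0.0647. MIR22HG, the host of a microRNA, was 544 ± 93.5 and 849 ± 130, with a log2 difference of -0.64 and a limma adjusted p of 0.0647. The others among the smallest 5 were CTD-2228K2.7 (-1.13), ALS2CL (-0.69) and FGD4 (-0.72), with limma adjusted p of 0.0647, 0.0991 and 0.0991.

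By camera at the preset correlation, 10 of 25 lists differed between the C-terminal and the other isoforms. Total reads were not a covariate in the camera tests. Cytosolic ribosomal proteins were higher by a median of 0.23 (camera adjusted p = 6.27e-17), complex I subunits by 0.24 (7.74e-10), histones by 0.59 (3.48e-10), mitochondrial ribosome genes by 0.20 (2.89e-10) and E2F targets by 0.27 (1.25e-05). Complexes II to V (0.20), G2/M genes (0.20), ATF4 genes (0.16) and glycolysis (0.12) were higher too, and mitochondrial DNA-encoded transcripts lower (-0.37, camera adjusted p = 3.61e-09). None of the 10 held, each with adjusted p = 0.639 with an estimated correlation. Adjusted over the list alone, 24 of 27 histones, 23 of 75 ribosomal proteins, 11 of 35 complex I subunits and 0 of 46 E2F targets passed with limma, and 0 members did over all genes tested. So did 7 mitochondrial ribosome genes, 4 ATF4 genes and 3 mitochondrial DNA-encoded transcripts over their lists alone. Members of a list are not independent, with estimated correlations of 0.96 for histones, 0.83 for ribosomal proteins and 0.64 for complex I. Without S811, T821 and T826, left out after the data were seen, the medians were 0.07 for complex I, 0.07 for ribosomal proteins, -0.05 for mitochondrial DNA-encoded transcripts, 0.27 for histones and 0.18 for E2F targets. In that setting 9 of the 10 lists passed at the preset correlation and 0 lists with an estimated correlation (lowest adjusted p = 0.756).

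The last comparison asked which gene lists follow E2F targets from library to library. G2/M genes, histones, repair genes and the RB family rose and fell with the E2F score across the 16 libraries, with Pearson r of 0.97, 0.94, 0.95 and 0.97 and Spearman rho of 0.94, 0.89, 0.91 and 0.94. Each had a permutation p of 1e-05, the smallest the permutations can give, and an adjusted p of 6e-05 over 24 lists. For Spearman rho the permutation p was 3e-05 for histones and 1e-05 for the other 3. The RB family shares 7 genes with the E2F list, and without them r was 0.92. Over the 14 isoforms alone r was 0.96, 0.92, 0.91 and 0.95, and without WT and T356, farthest from the median score, it was 0.92, 0.87, 0.86 and 0.91.

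A further 5 lists passed by Pearson r over 16 libraries but not over the 14 isoforms alone. These were ATF4 genes (r = 0.80, rho = 0.72, permutation p = 0.00031 and 0.00215), NuRD (0.77, 0.61, p = 0.00065 and 0.0144), p53 targets (-0.78, -0.61, p = 0.0009 and 0.0121), pigment markers (-0.78, -0.66, p = 0.00132 and 0.0069) and extracellular matrix (-0.74, -0.57, p = 0.00321 and 0.0228). Their adjusted p ran from 0.00149 to 0.00856 for r and from 0.0103 to 0.0609 for rho, by which extracellular matrix did not pass. Over the 14 isoforms r was 0.60, 0.60, -0.53, -0.59 and -0.43, with adjusted p of 0.09 or more. Without WT and T356 it was 0.61, 0.38, -0.53, -0.35 and -0.46, and 0 of the 5 passed. Complex I subunits had r = 0.10 and rho = 0.04 with the E2F score (permutation p = 0.669 and 0.892), and ribosomal proteins r = -0.02 and rho = -0.07 (permutation p = 0.935 and 0.798). The labels name no batch, so no relation could be recomputed within batches.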

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

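Within the 7 C-terminal and the 7 other isoforms, 30 measures were screened for a library far from the rest, 60 groups in all, of which 6 were picked out and chance would pick about 1 in 20, or 3.0. Tests of mitochondrial content, of nuclear RNA in the WT library and of gene span with WT left out were chosen after the results were seen. S811 stood highest among the C-terminal isoforms, with 334 genes 2-fold from the median of the other 15 samples, where the next had 38. T356 stood highest among the other isoforms with 122, where the next had 28. The glycolysis score was 0.41 in S811, where the next C-terminal isoform had 0.097. The pigment epithelium score was 0.23 in T356, where the next had 0.065. The heat shock score was 0.049 in S612, where the next had -0.029. The interferon score was -0.22 in T252, the lowest, where the next had 0.011.

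Nuclear OXPHOS and cytosolic ribosomal protein transcripts were higher than WT in S811, T821 and T826. Against protein-coding genes matched on transcript length, GC content and expression, the joined lists of 149 genes lay at the 100th percentile in each of the 3 libraries, with medians of 0.73, 0.35 and 0.36 where matched lists had 0.43, 0.21 and 0.21. Matching on gene span, length and expression gave the 100th percentile too, but the lists also passed the highest 2.5% in 6 of the other 12 libraries by length and in 10 of 12 by span, and matched genes stayed longer (979 against 835 bases). By the rule set beforehand, a place above the limit in each of the 3 libraries counted against both explanations. A condition on the other libraries was not part of that rule and was added to it. With it the tests decided nothing, since the limit did not set the 3 libraries apart. Length was taken from the longest transcript in a first run and from the principal protein-coding transcript here. Over 9915 other protein-coding genes, the Spearman correlation between length and the difference to WT was -0.34, -0.08 and -0.08 in S811, T821 and T826. It was positive in the other 12 libraries, from 0.07 to 0.23. Shorter transcripts thus tended to be higher against WT in these 3 libraries only, most in S811. With gene span in place of length the correlation was -0.29, 0.03 and 0.04 in S811, T821 and T826. It ran from 0.09 to 0.22 in the other 12 libraries. On that measure only S811 was negative. Whether a preference for short transcripts or a loss of intron-holding RNA accounts for the whole rise of the joined lists stays open. Transcripts of mitochondrial DNA did not move as 1 group. Protein-coding medians were at most -0.0312 against WT, while the ribosomal RNA MT-RNR2 was 9032, 6493 and 9755 against 2667. MT-RNR2 was above WT in all 14 isoforms, from 3898 in S249 to 10052 in S780, so it did not set these 3 apart. The other ribosomal RNA, MT-RNR1, was 310.2, 222.4 and 435.8 in S811, T821 and T826 against 221.5 in WT. In WT, MT-RNR2 was below MT-CO1, at 11675. How far library preparation removed ribosomal RNA from each library was not measured here. The values of MT-RNR1 and MT-RNR2 may therefore not reflect their amounts in the cells. A change in mitochondrial content stays open. A difference in RNA extraction or library handling and an effect of these phosphates, untested with 1 library each, stay open too.

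E2F targets were lower than WT in every isoform library, and WT was the deepest library. With WT thinned to 7192196 reads the median over isoforms was -1.277 ± 0.409 (SD, n = 14 isoforms). Thinning leaves the expected value of each gene unchanged and adds counting noise only, so it cannot decide on other effects of depth. In the 3 isoform libraries with less MALAT1 than WT, S811, T821 and T826, the medians were -1.23, -1.18 and -0.8971. This argues against a lower share of nuclear RNA in WT, as read from MALAT1 alone, as the whole explanation there. A part stays open. Their histone medians were -0.89, -1.07 and -1.04, against -1.64 over the 14 isoforms. Shorter transcripts also tended to be higher against WT in these 3 libraries. The histone medians therefore cannot tell a nuclear RNA effect from one of transcript length. RN7SK, also nuclear, went the other way, at 297648 in WT against a median of 219443 over the other 11 isoforms. A chance or culture effect in the single WT library remains open. So does the phosphorylation state of RB, since WT is also the only form that can carry several phosphates. The amount of RB1 transcript remains open too, since WT had the lowest value, 1714. S780, with 1755, had an E2F median of -0.90, but so did T826, with an RB1 value of 2579. RB1 amount was not tested for the gap to WT.

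Some genes stood at least 3-fold above the median of the others in a single library, with no other library more than 0.5 log2 above that median. There were 27 such genes among 12874 with a mean of at least 10, and 6 as far below. Insertion of the lentiviral construct in or near a gene is a candidate explanation, and longer genes would then be hit more often. The 25 protein-coding genes had a median span of 59075 bases, at the 97.12th percentile of lists matched on expression, which decided nothing by the rule set beforehand. Without the 10 genes high in WT, which include the cell-cycle genes PLK1, RRM2 and CDT1, the span was 110144 bases against 27972 and the percentile 99.91, which is consistent with insertion but cannot show it, since no insertion site was analysed here.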

How the results depend on the processing

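Alternatives without S811, T821 and T826 were chosen after the data were seen; the others were planned. Each count of genes 2-fold apart kept within 1.5 times its main value (570 for dCDK, 486.5 for the isoforms against WT, 10 against the other 15) except as follows. A mean of at least 200 gave 347, 295.5 and 5, by testing fewer genes, and 1.5-fold gave 1765, 1645 and 130.5. The count against the other 15 was 19.5 with a mean of at least 10 and 32 with no filter. For the gene lists, 388 of 400 alternatives that kept WT as the reference moved a median by less than its SD over the isoforms, 12 moved it further, and 0 turned a direction that stood apart from matched lists. With the median of the other samples as the reference the E2F median was -0.4037 in dCDK and 0.004503 over isoforms, by construction, since isoforms are then compared with each other. Directions also turned there for histones (0.005067), ATF4 genes (0.0004859) and pigment markers (-0.0002797) over isoforms, and for interferon (-0.03668) and NuRD (0.02022) in dCDK.

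For C-terminal against other isoforms, limma called 0 genes, and edgeR 0 and DESeq2 51 on recovered reads; the cause was not tested. Leaving out S608 and S612 gave 3. Leaving out each isoform in turn gave 0 to 20, the 20 without S788 and 3 without S612. The remaining alternatives, including the 3 libraries left out and total reads as a covariate, gave 0. With 0 genes called, the number of splits of the 14 isoforms with as many, 100 of 100 drawn from 1716, was fixed and shows nothing about chance. The highest other split gave 23 and held S811, T821 and T826 on one side.

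Of the 24 correlations with the E2F score, 9 passed over 16 samples, 8 to 12 under other pseudocounts, filters, scalings and Spearman rho, and 4 over the 14 isoforms alone. Leaving out each sample in turn gave 4 to 11, the 4 without WT. Without S811, T821 and T826 it was 13. The relations with G2/M genes, histones, repair genes and the RB family passed under 25 of 25 alternatives. No paired analysis was possible because each group held 1 sample. Depth limits single low genes most in S608, where 1 read is worth 1.46 normalised counts against 0.673 in WT.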

Other observations

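Several genes outside the lists differed from WT in all 14 isoforms and dCDK. The higher ones included C1S, a complement protease, at 56.9 ± 14.4 over the isoforms (SD, n = 14 isoforms) and 10.8 in WT. SLC16A4, a monocarboxylate transporter family member, was 241 ± 55.8 against 57.9, and MAP1A, a microtubule-associated protein, 1459 ± 275 against 450. Among the lower ones were MXD3, a MAX-binding repressor, at 75.4 ± 26.5 against 393, and NEURL1B, a ubiquitin ligase of the Notch pathway, at 74.0 ± 27.3 against 365. The mitochondrial ribosomal RNA MT-RNR2 was 2667 in WT, 4002 in dCDK and 6682 ± 2464 over the isoforms, from 3898 in S249 to 10052 in S780. MT-RNR2 was 9032 in S811 and 9755 in T826, where MT-CO1, a cytochrome oxidase subunit, was 8117 and 9165 against 11675 in WT. MT-CO1 belongs to the mitochondrial DNA list and lay on both sides of WT, reaching 20325 in T356. MDM2, a p53 target and regulator from the p53 list, was 1665 in WT and 3500 ± 656 over the isoforms. It ran from 1934 in S811 to 4408 in S612, and was at least 2-fold higher than WT in 9 isoforms. These genes were chosen after their values were seen, except those named by rule.

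The order of the isoforms by E2F targets could follow the amount of RB1 transcript, a hypothesis formed after both sets of values were seen. Over the 14 isoforms the Pearson r between log2 RB1 and the E2F score was -0.2014 (permutation p = 0.485) and Spearman rho -0.064 (permutation p = 0.830). Without S795 and S780, farthest from the median RB1, r was -0.15. The test does not decide. It left out WT, so it does not bear on the gap between WT and the isoforms. RB protein and its phosphorylation were not measured here.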
